A study of Mus musculus with 4 samples.

How the data were processed

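Gene expression was compared between mouse embryonic stem (ES) cells carrying a short hairpin RNA against exon 1 of Fmr1 (shFmr1) and ES cells carrying a random hairpin (shCT). Both hairpins were delivered by a lentivirus that also encodes GFP, and sorted cells were kept as mixed, non-clonal populations, per the labels' protocols. Per the labels, 4 Agilent 2-colour arrays, numbered as replicates 1 to 4, each held 1 shFmr1 RNA and 1 shCT RNA, with 0.2 µg of RNA at an RNA integrity number of 9. The shFmr1 RNA carried Cy5 on replicates 1 and 3 and Cy3 on replicates 2 and 4. The array titles place all 4 arrays on 1 slide, so slide could not be tested as a batch. The labels do not say that the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

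The values used were the authors' deposited table of 1 log ratio per array feature and array, read here as log2 ratios. No channel intensities were analysed here, so dim features could not be filtered. Undetected genes may sit near 0, but this could not be checked. The normalization method and the software behind the table are not given in the sources used here. The log base is not stated either. The largest absolute value, 5.84, exceeds 4.82, the largest log10 ratio that raw counts of a 16-bit scanner allow. This makes log10 unlikely but does not exclude it, since processed values need not keep to that range. Natural logs remain possible too. The medians of the 4 arrays were 0.01, -0.01, 0.02 and -0.02 and their SDs 0.345, 0.319, 0.370 and 0.414, in the order of the replicate numbers. The values had thus been centred before deposit. No value was missing.

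The direction of the ratios is not stated. Fmr1, the targeted gene, was negative on all 4 arrays although the dyes alternate, so the values had already been turned to a common direction, and shFmr1 over shCT is called the likely one. Fmr1 is then no independent check of that direction. Over genes, which are not independent replicates, arrays of the same dye orientation correlated at 0.0633 and 0.0438 and arrays of opposite orientation between -0.0532 and -0.0226.

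Features were named from a 2016 platform annotation. Of 45214 features, 33649 had 1 gene symbol, 56 had several and 11509 had none there, and the features with several or none were left out. Symbols were checked through gene identifiers against a reference gene table and 0 needed updating. Features of a gene were averaged on each array, which gave 19083 genes, 10740 of them with 1 feature. Features whose means over the arrays differed in sign were found for Fxr1, App, P4ha2, Odf1, Postn, Srebf2, Foxa2, Col4a1, Pax6, Col1a1 and Acta2. The gene means given below can hide such disagreement.

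Each gene was fitted with lmFit and eBayes (limma 3.58.1, R 4.3.3) with the shFmr1 ratio and a dye effect as coefficients. P-values were adjusted by the Benjamini-Hochberg method over all genes, with a threshold of 0.05. The 2 arrays of an orientation define the dye effect, so a gene with a large ratio in only 1 orientation can have a small p-value beside a large SD over the arrays. For Fmr1 an exact two-sided sign-flip permutation test was also run. The 29 gene lists were tested with camera at a preset correlation between genes of 0.01, adjusted over the lists, and again with an estimated correlation, with fry and with cameraPR. Camera and cameraPR set a list against the other genes, while fry asks whether the list itself changed. With an estimated correlation, camera takes its degrees of freedom from the arrays, and these are few. A call can thus be lost without correlation between its genes. The trophectoderm list had an estimated correlation of 0.0105, near the preset, yet its camera p went from 0.0470 to 0.186. Of 713 symbols in the lists, 655 were measured.

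The design, the gene lists, the rule for naming genes and the alternatives were fixed before the data were examined. The rule names Fmr1, Fxr1, Fxr2, App and 1 gene that is not reported here in any case, then the genes past the threshold and, where fewer pass, those with the smallest p-values up to 6 in each direction. It adds 4 members of each list called and up to 2 members of the other lists that pass when adjusted over the list alone. Genes named outside this rule were chosen after their values were seen, and they are Krt18, Foxa2, Col4a1, Sparc, Amn, Gata4, Afp, Ttr, Apoa1, Pou5f1, Sox2, Nanog, Pax6, Nes, Dlx1, Lin28a, Wnt3, Fgf8, Col1a1, Acta2, Gbp2, Gbp3, Igtp, Irgm1, Psmb8 and Psmb10.

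The alternatives were no dye term, other centring, scaling and quantile normalization of the arrays, other summaries of the features of a gene, tests on single features, other variance models and thresholds, other list tests, and leaving out each array in turn. With an array left out and the dye term kept, 1 array stands alone in its orientation. The residual spread then comes only from the 2 arrays of the other orientation. The number of arrays limits the precision, and the median gene had a 95% confidence interval of 0.24 to either side on the log2 scale. Both tests were run on simulated data for the same 19083 genes. With 50 genes changed at each size, the gene test called 4% at a log2 change of 0.5, 90% at 1, 96% at 2 and 100% at 3, with 8 false calls. So many changed genes loosen the adjustment, the variances came from the fitted prior, and dye effects were simulated at 0.5 of their size. These shares may thus not hold for the data, where Fmr1 at -1.37 missed the threshold. The list test called the 1 shifted list of 23 genes, shifted by -0.3, and 0 of 29 lists where none was shifted. The simulated genes were drawn independently of each other. This run thus cannot show how often the list test makes false calls where genes are correlated. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.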

Results

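The series asks what FMRP, the RNA-binding protein encoded by Fmr1, does in mouse embryonic stem (ES) cells, under the heading of neurogenesis. The data were 4 arrays that each set ES cells with the Fmr1 hairpin (shFmr1) against ES cells with a random hairpin (shCT), and they give 1 comparison. Values are log2 ratios of shFmr1 over shCT, given as mean ± SD over the 4 arrays. The log base and the direction are readings of the deposited values, and the direction is called likely.

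Fmr1 transcript was lower in shFmr1 cells on each array, with ratios of -0.86, -1.65, -1.34 and -1.61. The mean was -1.37 ± 0.36 (SD, n = 4), 2.58-fold lower, which leaves 38.8% of the control level. Its 2 features gave -1.81 ± 0.49 and -0.93 ± 0.26, or 28.6% and 52.6% of control. The 95% confidence interval of the gene ran from -1.63 to -1.10. Fmr1 had the second-smallest p-value of 19083 genes but missed the threshold (limma adjusted p = 0.156), and passed it when adjusted over the list alone of FMRP relatives and partners (adjusted p = 9.81e-05). The exact sign-flip permutation test gave p = 0.125, two-sided, the smallest that 4 arrays allow. With the dye term kept, the limma adjusted p was 0.0382 without replicate 1, 0.0327 without replicate 2, 0.0630 without replicate 3 and 0.0832 without replicate 4, and without a dye term it stayed above the threshold whichever array was left out (lowest 0.152, without replicate 1). Read as natural logs, the Fmr1 values would become -1.97 on the log2 scale.

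The paralogs Fxr1 and Fxr2 did not pass the test, at -0.07 ± 0.25 and 0.41 ± 0.96 (n = 4). One of the 4 Fxr1 features gave -0.68, and the sign of Fxr1 turns with the median over its features (0.05). The Fxr2 mean rests on replicate 4, which read 1.85. App, the amyloid precursor gene and a reported FMRP target, averaged 0.00 ± 0.22 over 13 features, with a 95% confidence interval from -0.23 to 0.23.

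Among all genes, the smallest p-values toward lower levels besides that of Fmr1 belonged to Hamp2, a hepcidin gene (-1.20 ± 1.28), and Krt19, a keratin of simple epithelia (-1.10 ± 0.44). Srgn, which encodes the proteoglycan serglycin, followed at -1.60 ± 1.60, then Gbp2b, an interferon-inducible GTPase (-0.59 ± 0.22), and Chst1, a carbohydrate sulfotransferase (-0.57 ± 0.41). Toward higher levels they belonged to Setmar, a histone methyltransferase (1.28 ± 1.01), Tubb2b, a beta-tubulin of developing neurons (0.55 ± 0.11), P4ha2, a subunit of collagen prolyl hydroxylase (0.51 ± 0.53), Napsa, an aspartic protease (0.53 ± 0.23), Odf1, a sperm tail protein (0.65 ± 0.68), and Taf8, a TFIID subunit (0.62 ± 0.26). None of these genes passed the test, with limma adjusted p of 0.156 for Hamp2, 0.274 for Krt19, 0.581 for Srgn and 0.973 for the others. The ratios of Hamp2 and Srgn came mainly from the arrays with shFmr1 in Cy5, at -2.42 and -2.18 against -0.02 and -0.17 for Hamp2, and at -3.41 and -2.44 against -0.53 and -0.02 for Srgn. P4ha2 and Odf1 were high mainly with shFmr1 in Cy3, at 1.01 and 0.92 against -0.004 and 0.10 for P4ha2. For Odf1 these values were 1.47 and 0.93 against 0.02 and 0.17. Krt19, Chst1 and Setmar also had an unadjusted limma p under 0.05 for the dye effect. The features of P4ha2 (-0.07 and 1.08) and of Odf1 (-0.03 and 1.32) disagreed.

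In the whole transcriptome, 0 of 19083 genes passed adjusted p of 0.05 with limma, and 719 had an unadjusted p under 0.05 (327 higher, 392 lower), where 5% of the genes would be 954. For the dye effect in the same fit, 0 genes passed and 1238 had an unadjusted p under 0.05, more than for shFmr1. Fitted without a dye term, 0 genes passed and 621 had an unadjusted p under 0.05. The share of genes with the same sign on all 4 arrays was 11.3%, against 12.5% by chance. Leaving out 1 array with the dye term kept, which leaves few degrees of freedom, gave 25 genes without replicate 1, 87 without replicate 2, 10 without replicate 3 and 0 without replicate 4, and without a dye term 0 genes passed whichever array was left out. Setmar (adjusted p = 0.0315), Hamp2 (0.0262) and Krt19 (0.0283) passed limma's test without replicate 2. In that fit replicate 4 stood alone in its orientation, so its error did not enter the residual spread.

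**Figure D1:**
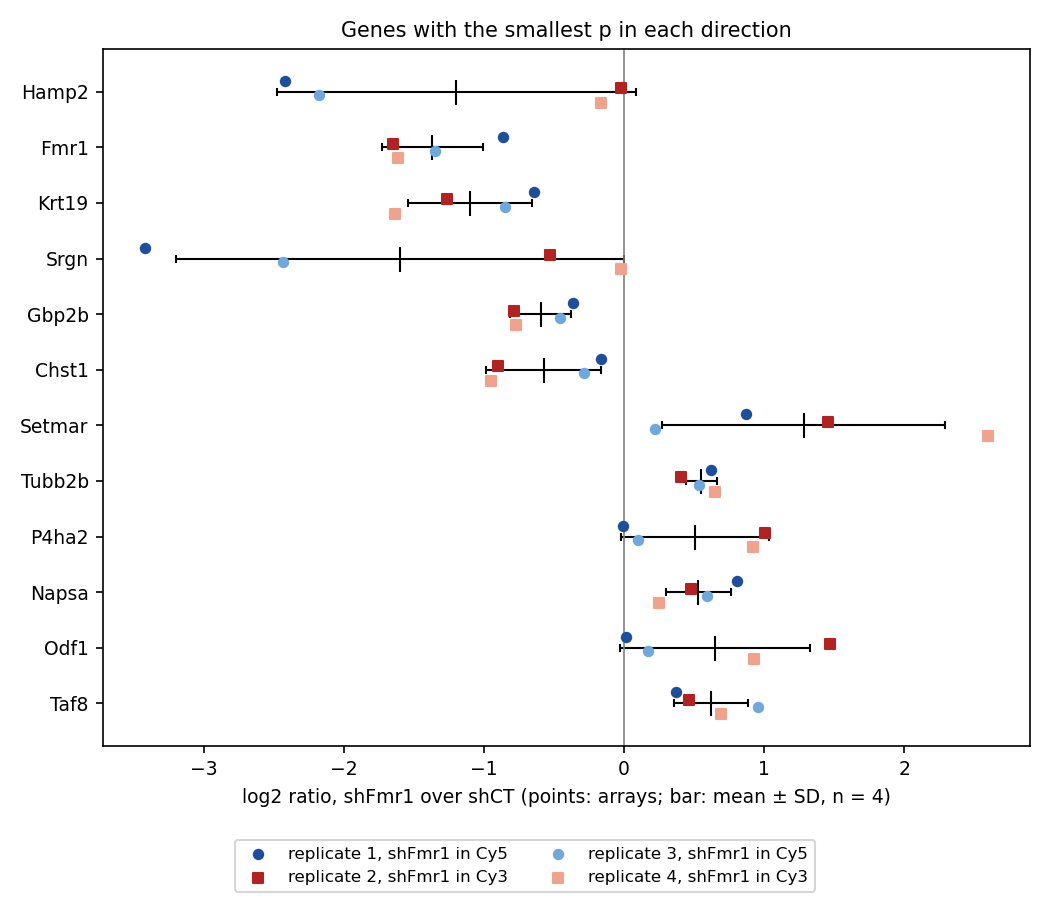
Log2 ratio of shFmr1 over shCT (horizontal axis) for the 6 genes with the smallest p in each direction, with points for the 4 arrays coloured by replicate and shaped by dye, and bars for the mean ± SD. Fmr1 lies between -1.65 and -0.86 on the 4 arrays. Hamp2 and Srgn are low mainly with shFmr1 in Cy5, and P4ha2 and Odf1 are high mainly with shFmr1 in Cy3. Krt19, Chst1 and Setmar, among others, lie further from 0 with shFmr1 in Cy3. None of the genes passed adjusted p of 0.05.

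Markers of primitive and visceral endoderm, the extraembryonic lineages that ES cultures can also form, were lower as a group. Of 23 measured genes 19 were negative, with a median of -0.26, and the list differed from the other genes (camera adjusted p = 6.93e-10). The call was lost with an estimated correlation (adjusted p = 0.753, or p = 0.0343 before adjustment over the lists) and with fry (adjusted p = 0.349). The estimated-correlation test has few degrees of freedom here, so its loss does not show that correlated genes made the call. Rhox5, a homeobox gene, averaged -1.44 ± 0.82, Cubn, an endocytic receptor of visceral endoderm, -1.01 ± 0.96, Cited1, a transcriptional coregulator, -0.49 ± 0.18, and Srgn is given above. Amn, the partner of cubilin, averaged -0.34 ± 0.09, the endoderm factor Foxa2 -0.44 ± 0.47 over 10 features of which 9 were negative, and the matrix genes Sparc and Col4a1 -0.51 ± 0.52 and -0.39 ± 0.37. These 8 members passed when adjusted over the list alone and 0 passed over all genes, while Gata4, Afp, Ttr and Apoa1 were positive. The median of the list was -0.0976 with 1 feature per gene and -0.0740 over single features, still called, and -0.16 without replicate 1 with the dye term kept. The list medians on the arrays were -0.33, -0.03, -0.23 and -0.13 in replicate order, and the dye coefficient of the same list also passed (camera adjusted p = 0.00658).

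**Figure D2:**
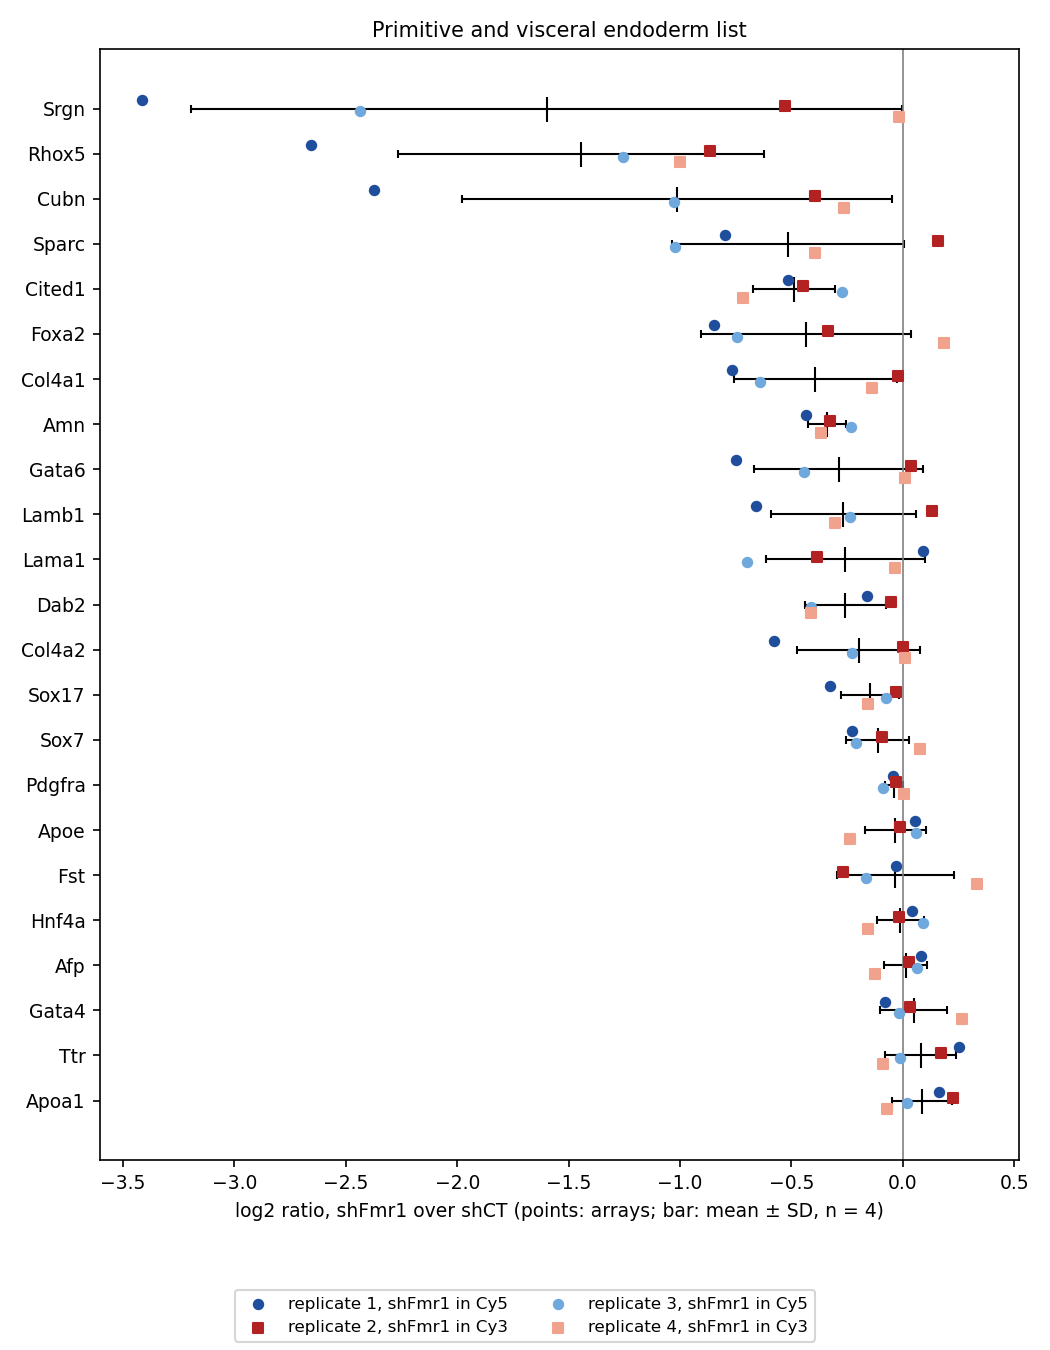
Log2 ratio of shFmr1 over shCT (horizontal axis) for the 23 measured members of the primitive and visceral endoderm list, with points for the 4 arrays coloured by replicate and shaped by dye, and bars for the mean ± SD. Of the 23 means 19 are negative, and for Srgn, Rhox5 and Cubn the lowest point is replicate 1.

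Genes of formative and primed pluripotency, the state between naive ES cells and the differentiating epiblast, were lower as a list of 14 (median -0.07, 9 negative, camera adjusted p = 0.0243). With an estimated correlation the adjusted p was 0.753. The members with the smallest p were Fgf5 (-0.75 ± 0.49), the kinase gene Pim2 (-0.89 ± 0.69), the POU factor Pou3f1 (-0.58 ± 0.61) and the DNA methyltransferase Dnmt3b (-0.41 ± 0.74). Dnmt3b read -0.76 and -1.27 with shFmr1 in Cy5 but 0.08 and 0.33 with shFmr1 in Cy3. None of the 14 passed when adjusted over the list alone or over all genes, and 4 had an unadjusted p under 0.05. The call was lost without replicate 2 (adjusted p = 0.267) or replicate 3 (0.290) with the dye term kept. The list medians on the arrays were -0.08, 0.04, -0.21 and 0.02 in replicate order. The list median was thus below 0 only on the arrays with shFmr1 in Cy5. Single members differed from this, and with shFmr1 in Cy3 Fgf5 read -1.17 and -0.55 and Pim2 -1.01 and -0.53. Pou3f1 read -0.64 and 0.04 there. The dye coefficient of the list did not pass camera at adjusted p of 0.05, which does not exclude a dye effect on it.

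Cholesterol synthesis genes were slightly lower, with 16 of 18 negative and a median of -0.09 (camera adjusted p = 0.0308). The adjusted p was 0.753 with an estimated correlation. Srebf2, the transcription factor of the pathway, averaged -0.15 ± 0.06 and the enzyme genes Sc5d, Nsdhl and Cyp51 -0.16 ± 0.17, -0.14 ± 0.14 and -0.15 ± 0.18, and 0 of the 18 had an unadjusted p under 0.05. Leaving out replicate 2, 3 or 4 with the dye term kept ended the call (adjusted p = 0.0668, 0.220 and 0.289). Replicate 4 had a list median of -0.28 and replicate 1 of -0.002. The dye coefficient of the same list also passed camera at adjusted p of 0.05.

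Markers of embryonic fibroblasts, which can serve as feeder cells, were higher as a list of 19 (median 0.13, 14 positive, camera adjusted p = 0.0444), a call lost with an estimated correlation (adjusted p = 0.753). Col5a1 averaged 0.32 ± 0.23, the matrix genes Postn and Lox 0.22 ± 0.13 and 0.23 ± 0.37, and the intermediate filament gene Vim 0.19 ± 0.24, with 0 past the threshold over the list alone. The list varied between arrays, with medians of 0.26, 0.28, 0.02 and -0.19, and so did its members Col1a1 (2.19, 0.54, -0.05 and -0.99) and Acta2 (1.80, 0.90, -0.18 and -0.52). Without replicate 1 or replicate 2, dye term kept, the adjusted p was 0.866 and 0.572. With 1 feature per gene the median turned to -0.0029 and the call was lost.

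**Figure D3:**
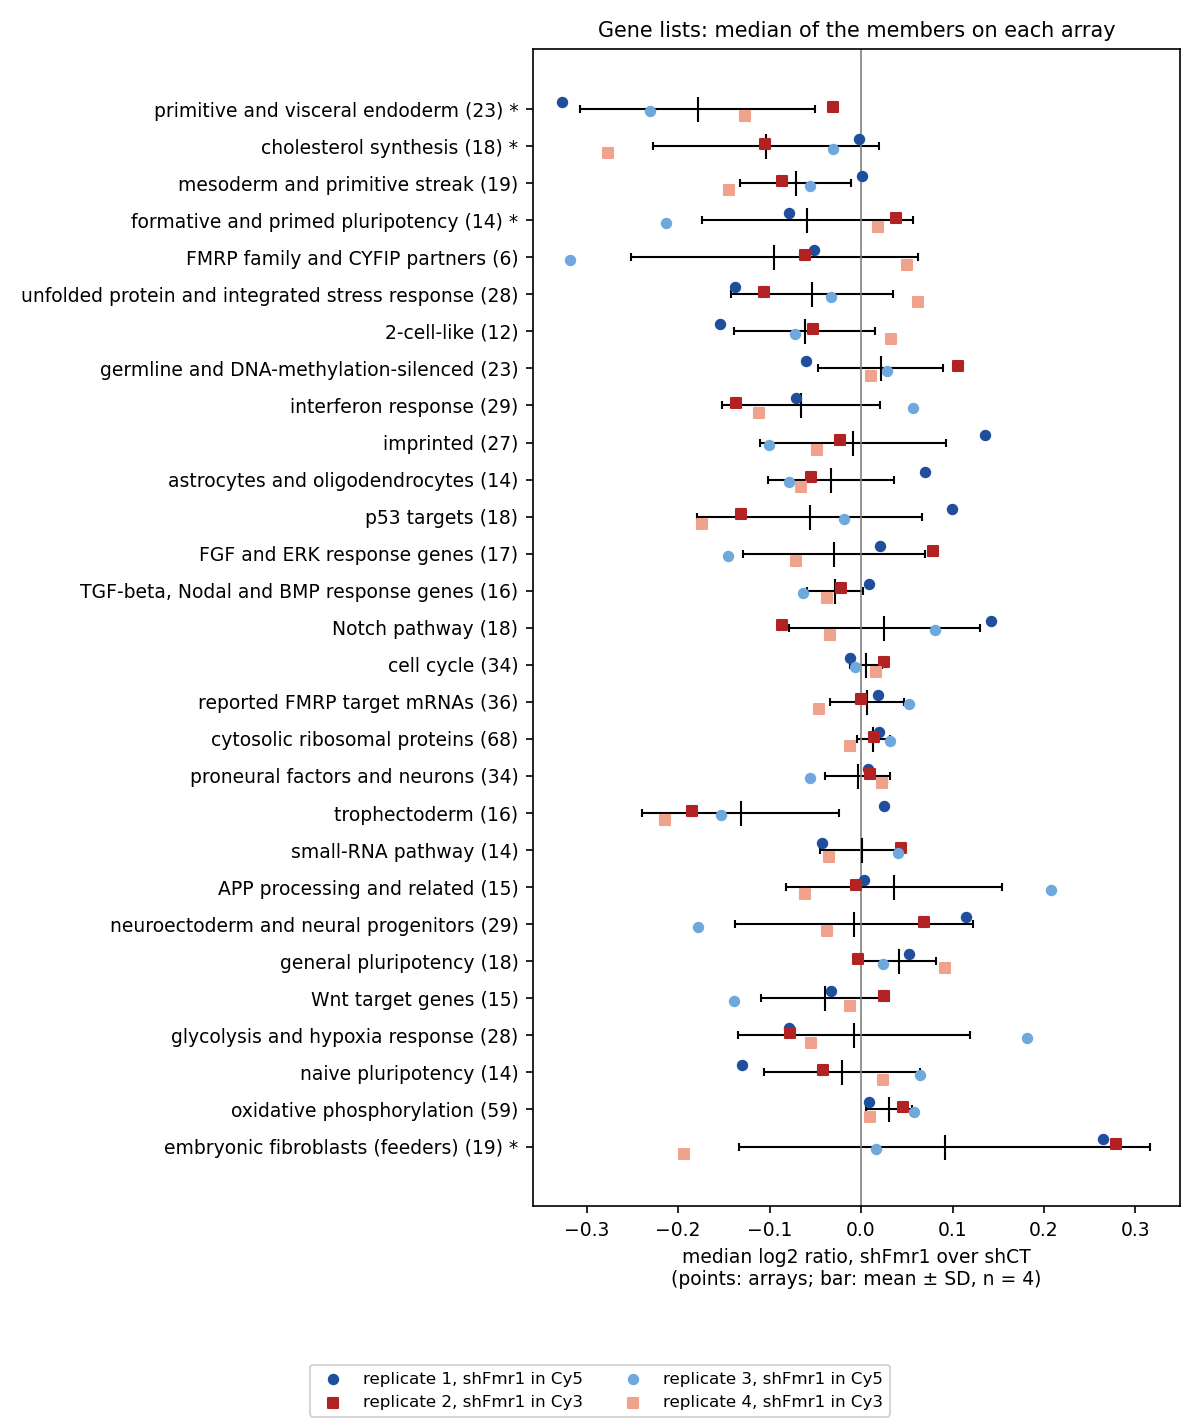
Median log2 ratio of shFmr1 over shCT (horizontal axis) of the members of each of 29 gene lists on each array, with the number of measured members in parentheses. Points are the 4 arrays, coloured by replicate and shaped by dye, bars the mean ± SD of the 4 array medians, lists are sorted by the median of their gene means, and asterisks mark the 4 lists with camera adjusted p under 0.05.

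No list of neural genes passed the test. The 29 neuroectoderm and neural progenitor genes had a median of 0.01 (camera adjusted p = 0.847) and the 34 proneural and neuronal genes 0.01 (0.651), with 0 members past the threshold over either list alone. Pax6 averaged 0.19 ± 0.14, Dlx1 0.46 ± 0.21 and Nes, an intermediate filament gene of neural progenitors, -0.46 ± 0.49. Astrocyte and oligodendrocyte genes had a median of -0.03 (0.847), Notch pathway genes had 9 of 18 negative (0.651), and APP processing genes a median of 0.01 (0.847). The 36 reported FMRP target mRNAs had a median of 0.00, with 17 negative, 0 with an unadjusted p under 0.05 and a camera adjusted p of 0.827. FMRP relatives and partners, a list that holds Fmr1 itself, had a median of -0.07 (0.129).

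The lists of general and naive pluripotency genes did not pass either. The general list of 18 genes had a median of 0.02 (camera adjusted p = 0.478) and the naive list of 14 genes 0.02 (0.874). Pou5f1 averaged -0.10 ± 0.16, Sox2 0.16 ± 0.32, Nanog 0.33 ± 0.52 and Lin28a 0.26 ± 0.11, and without replicate 4, dye term kept, Sox2 turned to -0.03. Mesoderm and primitive streak genes had a median of -0.07 (0.186), with Wnt3 at -0.43 ± 0.22 and Fgf8 at -0.39 ± 0.34. Trophectoderm genes had a median of 0.01 and a mean of -0.15 (0.181), and the keratin genes Krt19, Krt8 (-1.16 ± 0.61) and Krt18 (-0.82 ± 0.56), which many simple epithelia express, passed when adjusted over the list alone (adjusted p = 0.000688, 0.00841 and 0.0469). The genes of the 2-cell-like state had a median of -0.04 (0.478).

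Egr1, an immediate early gene, averaged -0.59 ± 0.12 and passed when adjusted over the list alone of FGF and ERK response genes (adjusted p = 0.0109), whose median was -0.03 (camera adjusted p = 0.478). P4ha2 passed in the same way within the glycolysis and hypoxia list (0.0283), whose median was 0.02 (0.722). The P4ha2 ratio behind this call came mainly from the arrays with shFmr1 in Cy3, at 1.01 and 0.92. With shFmr1 in Cy5 it read -0.004 and 0.10. Interferon response genes had a median of -0.03 (0.181), p53 targets -0.03 (0.214), stress response genes -0.06 (0.186) and oxidative phosphorylation genes 0.04 (0.120). Imprinted genes had a median of -0.03 (0.651), germline genes silenced by DNA methylation -0.03 (0.659), Wnt target genes 0.02 (0.651) and TGF-beta, Nodal and BMP response genes -0.01 (0.967). Cytosolic ribosomal protein genes had a median of 0.00 (0.659), small-RNA pathway genes 0.01 (0.967), and cell cycle genes had 18 of 34 negative (0.722). Median, mean and test differed in sign for the naive pluripotency, trophectoderm, astrocyte and oligodendrocyte, cell cycle, Wnt, TGF-beta, Notch and small-RNA lists, none of which was called. With an estimated correlation or with fry, 0 of the 29 lists passed. Given its few degrees of freedom, the estimated-correlation test cannot decide whether correlation between genes explains the calls.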

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

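The test of single features below was chosen after discordant features of App had been seen. On 3 of 83 results, 54 named genes and 29 lists, 1 array lay apart from the others by Dixon's criterion, where chance alone gives about 1 in 20, or 4.15. Fxr2, a paralog of Fmr1, read 1.85 in replicate 4 and between -0.21 and 0.05 in the others. The astrocyte and oligodendrocyte list had a median of 0.0697 in replicate 1 and between -0.08 and -0.05 in the others, and the glycolysis and hypoxia list a median of 0.18 in replicate 3 and between -0.08 and -0.05 in the others.

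Fxr2 is measured by 1 feature. Over the 4 arrays 978 values lay beyond 2 in size, on 960 of 45214 features. Of these values 89.7% had Cy3 brighter if the ratios are shFmr1 over shCT, and Cy5 brighter if they run the other way. Only 17 features exceeded that size on 2 or more arrays, against 7.50 by chance. Where an accession had 5 or more features, 83 values exceeded 1.5, and the other features of the accession reached a median share of 0.0304 of the value, as a spot-level artefact would give. In 27 of the 83 the others reached at least 0.5 of it, so not every such value stood alone. In the shFmr1 over shCT reading, 52 of the 83 had Cy3 brighter and 31 Cy5, a mix unlike that of the 978. A spot-level artefact may thus lie behind the Fxr2 value, which has no second feature to test it, and a real change in the shFmr1 RNA of replicate 4 was not tested.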

How the results depend on the processing

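The log base, the single-orientation fits and the endoderm list without its 8 lowest-p members were chosen after seeing the data. Gene counts stayed at 0 in each of the 11 settings run apart from leaving out arrays, and Fmr1 kept its direction in all, at -1.97 if read as natural logs. Leaving out 1 array gave 0 to 87 changed genes, 0 to 75 higher, 0 to 25 lower, Fmr1 from -1.54 to -1.25 and 1 to 8 lists called. The endoderm list was called in all 8 of these fits, from -0.26 to -0.13, and its median was -0.0976 with 1 feature per gene and -0.0740 over single features, called in both. The other ranges were -0.156 to -0.0692 for the formative list, 0.0145 to 0.272 for fibroblasts, -0.140 to -0.00511 for cholesterol synthesis, -0.0747 to 0.0990 for App, -0.198 to 0.0489 for Fxr1, -0.0700 to 0.858 for Fxr2, -0.0304 to 0.355 for Sox2 and -0.167 to 0.981 for Col1a1. Lists called numbered 5 over single features, 3 with quantile normalization and 3 with the median over features. They numbered 1 with 1 feature per gene, 1 at adjusted p of 0.01, 0 with an estimated correlation, 0 with fry and 2 with cameraPR. The calls of the endoderm (-0.26), formative (-0.0709), fibroblast (0.13) and cholesterol (-0.0864) lists were lost with an estimated correlation and with fry, where the medians do not move. The formative and fibroblast calls were also lost with cameraPR, those of formative, fibroblast and cholesterol at adjusted p of 0.01, and the fibroblast call with quantile normalization (0.14) and with the median over features (0.13). With 1 feature per gene the formative list (-0.0557) and the cholesterol synthesis list (-0.0615) lost their calls and the fibroblast list reversed (-0.0029). Without its 8 lowest-p members the endoderm list had -0.0392 and lost its call (adjusted p = 0.0652, range over all settings 5.73e-10 to 0.753), and with shFmr1 in Cy5 or Cy3 alone it kept it (-0.31 and -0.0864). App reversed with quantile normalization (-0.0129) and the median over features (-0.0155), and Fxr1 with that median (0.0493). With 1 feature per gene Fxr1 (0.0578), P4ha2 (-0.0702), Odf1 (-0.0258), Postn (-0.0647), Srebf2 (0.0632), Col1a1 (-0.0856) and Acta2 (-0.13) reversed. For the reversals the cause was not tested. Of 54 named genes 44 never reversed, and 5 passed the threshold in some fit without 1 array, Rhox5 without replicate 3 (adjusted p = 0.0486). Each ratio sets 1 shFmr1 RNA against 1 shCT RNA within 1 array, so the fit is itself paired by array. No pairing between groups of arrays was possible, because the labels give 1 group of arrays. A filter on intensity was not run, since no intensities were analysed here, nor one on missing values, since none was missing. Signal over background is unknown.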

Other observations

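The tests in this part were chosen after the results were seen, except the counts over sign patterns. For a general loss of differentiated cells and for a general interferon response, the bound that would exclude each was also reworded after its result was known, because undetected genes sit near 0. Under the first wording the tests would have counted against both. The bound for a dye bias of the endoderm list was reworded too, as the first left out that a dye effect cancels over balanced arrays, and under it that test decided nothing.

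Genes for interferon-inducible GTPases and the immunoproteasome were low beside Gbp2b, with Gbp2 at -0.60 ± 0.59, Gbp3 at -0.53 ± 0.20, Irgm1 at -0.38 ± 0.08, Igtp at -0.38 ± 0.19, Psmb8 at -0.53 ± 0.27 and Psmb10 at -0.40 ± 0.28 (n = 4). None passed over all genes. The hypothesis that the family is lower was first tested on 21 genes chosen by name pattern (median -0.14, 15 negative, camera p = 2.07e-07, or p = 0.0295 with an estimated correlation), and as first written this counted in its favour. The members include the 6 genes that prompted it (Gbp2b, Gbp2, Gbp3, Irgm1, Psmb8 and Psmb10), so it cannot decide. The 15 other members, Igtp among them, had a median of -0.0258 with 9 negative, and were not called by camera at 0.05. That median lay at percentile 23.9 of 10000 random lists. The 6 left out were chosen by their outcome, so the rest cannot decide whether the family is lower or only the genes noticed. The 25 other interferon response genes had a median of -0.0288, which leaves a general response difference open, and shared probe sequence between GTPase paralogs was not tested.

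The lower endoderm list was weighed against 3 alternatives. A dye bias as its cause would give opposite signs in the orientations and cancel in the mean of the balanced arrays. The list median was negative in both, at -0.0864 with shFmr1 in Cy3 and -0.31 in Cy5. This argues against a dye effect of 1 size as the only cause. The Cy3 median lay just within the middle 95% of random lists, from -0.0869 to 0.0748, so its sign alone decides little. The gap between the Cy3 and Cy5 medians stays open. Arrays of opposite orientation correlated at a mean of -0.0377 over genes, as a dye effect would give. Replicates 1 and 3 and replicates 2 and 4 could also share a culture. Without the 8 members of lowest p the other 15 had a median of -0.0392, which decides nothing about a few members carrying the list, since the 8 were chosen by their outcome. Of 4 other lineage lists 3 were not below random lists, which does not exclude a general loss of differentiated cells, and a loss of endoderm-like cells upon Fmr1 knockdown remains an open hypothesis.

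A gain or loss of a whole chromosome in 1 population would shift all of its genes. The largest shift of a chromosome median on any array was 0.0277 over 20 chromosomes and 19027 genes. An extra copy in every cell would give 0.585 if every gene were detected. Undetected genes could hold a median nearer 0, so this argues only against a shift of about that size. One chromosome passed the rank test over genes (adjusted p = 0.0296), at a median difference of 0.0107.

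Of the 16 sign patterns of 4 arrays, 3 are balanced against the dye term when mirror images count once, the real one included, which is too few for a share under 0.05. All 3 gave 0 changed genes, the highest other included, and a count of 0 cannot be undercut, so this says nothing about chance. For lists called, the real pattern gave 4 and the highest other 5, so 2 of the 3, the real one included, reached 4. The pattern with 5 set replicates 1 and 2 against 3 and 4 and called the neuroectoderm, fibroblast, imprinted, glycolysis and hypoxia, and stress response lists.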
